A study of Glycine max with 16 samples.

How the data were processed

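Small RNA was sequenced on an Illumina HiSeq instrument from 16 soybean seed coat libraries, in 8 groups of 2 biological replicates per the labels. Per the labels' protocols, seed coats were dissected by hand into pigmented and non-pigmented parts, and RNA was isolated by a method adapted to tissue rich in proanthocyanidins. Each deposited file lists every distinct sequence of 16 to 39 nt with its raw read count, 1 file per library. The values are whole-number counts of reads per sequence as the authors deposited them, with no normalization. The trimming tool, the read filters and any mapping are not given in the sources used here.

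The counts are interleaved with bare sequence lines, so they were handled as a file of another kind than a plain count table. A quasi-likelihood count test had been planned, and limma was used in its place with TMM scaling factors computed in R. Reads of 18 to 30 nt formed the library total for scaled levels (CPM, reads in every 1e6 reads). Sequences (tags) at 5 CPM or more in at least 2 libraries were tested, 30762 in all. TMM factors trimmed 30% of log ratios and 5% of mean levels at each end, and ranged from 0.801 to 1.30. The limma voom model held 1 mean per group over all 16 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

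Reads were assigned to 50 families (73 sequences), listed before the data were examined, when their first 18 nt matched a listed sequence. The families include miRNAs, a trans-acting siRNA and 5′ fragments of tRNA, and 44 families reached 1 CPM in at least 2 libraries. Families were grouped in fixed lists and tested one by one and with fry, which asks whether a list's members move on balance in a single direction or, in its mixed form, in either direction. No genome sequence was used here, so tags have no positions and were not matched to genes. The gene table of Glycine_max_v4.0 served only to count symbols: it holds 659 MIR symbols and 17 CHS symbols, 1 of them a pseudogene.

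The planned match of 20 to 24 nt reads to soybean chalcone synthase (CHS) genes was therefore replaced, after the data were examined, by a match to the CHS protein. A read was called CHS-coding when every codon of at least 6 in any frame, on either strand, matched a stretch of a legume (alfalfa) CHS protein of 389 residues. That protein sequence was written from general knowledge and was not checked against a database. Soybean codons that encode another residue are missed, and the CHS copies cannot be separated. Matches to the same protein read backwards gave a background. Reads with an uncalled base were left out of tags, families and CHS-coding reads but stayed in the totals. CHS-coding CPM, the shares of 5 read lengths and 12 shares of first bases were compared with two-sided exact permutation tests, in which parts were rearranged within line and stage, or isolines among the 8 Clark libraries.

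Library titles carry numbers that fall in 4 runs of consecutive values, 36 to 39, 47 to 50, 64 to 67 and 106 to 109, here called sets. Each pair of pigmented and non-pigmented libraries lies within a single set. The sets 36 to 39 and 47 to 50 each hold a Williams pair and a Clark i-i k1 pair. The set 64 to 67 holds all i-k K1 libraries and no others, and the set 106 to 109 holds the Williams replicate 2 libraries of both stages. The first principal component took 62.3% of the variance and set the 4 Williams replicate 2 libraries (−278 to −262) apart from the other 12 (−31.8 to 148). Their mean correlation with other libraries was 0.406 to 0.463, against 0.557 to 0.732 for the others. Replicate numbers come from the titles. Deviations of same-numbered pigmented and non-pigmented libraries from their group means correlated across tags at 0.932, 0.954, 0.185 and 0.805 in the 4 line and stage sets. All lay above the minimum of 0.1 set beforehand, so same-numbered libraries were treated as pairs. In Williams and Clark i-i k1, replicates 1 and 2 came from different library sets, so the correlation can reflect the set. It was lowest in Clark i-k K1, where all libraries share a single set. It does not show that same-numbered libraries came from the same plants. The fit with each pair as a block is called the paired fit, and its values are printed where they change a call. Between isolines or stages, where no pairs exist, that fit held a common term for replicate 2 instead. No 2 replicates agreed within sampling noise: chi-square per degree of freedom was 12.5 or more over tags with at least 20 reads.

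The rule for naming families and tags was set before the data were examined. It took families past the threshold at a mean of 10 CPM or more, up to 8 per direction, and up to 3 tags per direction at 50 CPM or more, by size of the fold change. It was written for the unpaired fit; its use on the paired fit was decided afterwards, and families below 10 CPM that are named were chosen after their values were seen. Alternatives covered other scaling factors, no factor, other filters, exact tag matches, 20 to 24 nt tags, the paired fit and each library left out. A limma trend fit on log2(CPM + 1) and several others were added later.

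The procedure was tested on simulated counts for the comparison of parts averaged over the 4 sets of line and stage, on 30762 tags with 200 changed tags and a dispersion of 0.05. Where simulated pairs differed as the libraries do, the unpaired fit recovered 0% of tags changed 2-fold, 0% of those changed 4-fold and 19.7% of those changed 8-fold, with 0 false calls. The paired fit recovered 86.6%, 97.0% and 98.5%, with 3 false calls. Both simulated libraries of a pair had the same mean except in changed tags, so pairing removed all replicate differences by construction. In the real libraries pair deviations correlated at only 0.185 in Clark i-k K1, so these rates may not hold for them. Where simulated pairs were alike, both fits recovered at least 91.0% at every fold size, with 13 false calls unpaired and 11 paired. Replicates are described as biological in the design, but how far their plants were apart is not stated, so p-values measure the spread between these samples. PCR reads without molecular identifiers are not independent molecules, so a floor given for a count of 0 covers counting error only.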

Results

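Small RNA was profiled in 16 libraries from developing seed coats of soybean, to set pigmented tissue against adjacent tissue without pigment. In the cultivar Williams, the pigmented hilum (the scar where the seed joins the pod) was compared with the rest of the seed coat at 25 to 50 mg and at 50 to 100 mg fresh seed weight. In 2 isolines of the cultivar Clark, labelled i-k K1 and i-i k1, the pigmented saddle around the hilum was compared with the rest at 100 to 200 mg. Each of the 8 groups had 2 libraries. Pigmented tissue was always the hilum or the saddle, so effects of pigment and of position in the seed coat cannot be told apart. The series title names the I and K1 loci and Argonaute5, a protein that binds small RNAs. The I locus is known as a cluster of CHS genes in inverted orientation, whose siRNAs silence CHS, the entry enzyme of flavonoid pigment synthesis.

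The libraries held 13871064 to 74061701 reads, of which 10022262 to 62267318 were 18 to 30 nt long. Reads of the listed miRNA families made 0.133% to 2.70% of the total per library. The 4 i-k K1 libraries were the shallowest, and 12.7% ± 0.00945 (SD, n = 4) of their reads had an uncalled base, against 0.158% ± 0.0885 (SD, n = 12) elsewhere. Replicates correlated across tags at 0.847 to 0.976 on the log2 scale in Clark, but at 0.322 to 0.4998 in Williams. Replicates came from different library sets in Williams and in Clark i-i k1 alike.

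CHS-coding small RNA was lower in pigmented than in non-pigmented tissue of every line and stage. In Williams at 25 to 50 mg it reached 859 ± 240 CPM in the hilum and 2407 ± 687 CPM in the rest (SD, n = 2 each). At 50 to 100 mg the levels were 766.5 ± 999 and 3471 ± 3423 CPM. In the Clark saddle these reads were scarce, with 37.2 ± 12.4 against 352 ± 213 CPM in i-k K1 and 36.9 ± 1.73 against 1092 ± 114 CPM in i-i k1. Part of the saddle reads may be background. Matches to the reversed protein equalled 15.7% to 39.9% of CHS-coding reads in the saddle libraries, and 0.568% to 8.78% in the rest of the Clark seed coat. At 21 nt the saddle shares were 7.05% to 23.6%. In each saddle library the 20 nt antisense matches to the reversed protein exceeded the CHS-coding reads of that class, such as 458 against 84 in i-i k1 replicate 1. Those matches cannot all stand for background within the CHS-coding reads. The mean difference was 8.83-fold (log2 difference −3.14, two-sided exact permutation p = 0.0031), with the pigmented part lower in 8 of 8 pairs.

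The pair folds ran from 2.79 to 32.9. Williams pairs gave 2.79 and 2.81 at 25 to 50 mg and 17.5 and 4.0 at 50 to 100 mg, in order of replicate. Clark i-k K1 pairs gave 17.7 and 4.38, and i-i k1 pairs 26.5 and 32.9. With reads that match the reversed protein subtracted the Clark folds were 28.5 and 5.27 in i-k K1 and 34.6 and 38.8 in i-i k1. The Williams folds then ran from 2.81 to 19.7. In the Clark saddle and in Williams hilum replicate 1 at 50 to 100 mg this likely subtracts too much, for the reason given above. As a member of the limma family table, CHS-coding RNA fell by 3.23 on the log2 scale (SE 0.70, adjusted p = 0.0173) over all 4 sets. Single sets passed the limma threshold in the paired fit alone, with adjusted p of 0.0065, 8.5e-08, 6.1e-08 and 4.2e-20, against 0.990, 0.628, 0.980 and 0.134 unpaired. These p-values rest on a spread shared over all sets and borrowed in part from the other families. They do not measure the spread between the few pairs of a single set.

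**Figure D1:**
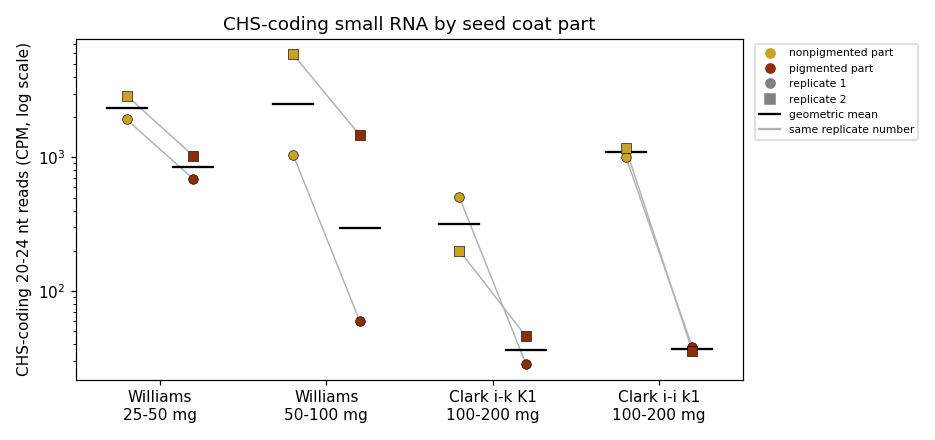
CHS-coding reads of 20 to 24 nt per library in CPM on a log axis, by line, stage and seed coat part; symbols give the replicate, grey lines join libraries of the same number and black bars are geometric means of 2 libraries. The pigmented library lies below its partner in 8 of 8 pairs.

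The CHS-coding reads were mostly 21 nt long in non-pigmented tissue, with a mean share of 60.1% to 75.2% by group, a size typical of Dicer-like siRNA products. The hilum means were similar, at 79.3% and 70.1%, though the later stage had 61.7% in replicate 1 and 78.6% in replicate 2. In the Clark saddle the share was 35.0% in i-k K1 and 37.7% in i-i k1. Single saddle libraries had 32.1% to 43.1%, against 70.5% and 49.7% in the non-pigmented i-k K1 libraries. So the few saddle reads showed less of this size profile. These shares include any background, and matches to the reversed protein were most frequent at 20 nt in the saddle. Reads of both strands occurred, and antisense made 25.9% to 47.7% of the 21 nt class in non-pigmented tissue, 43.1% and 40.05% in the hilum, and 15.4% and 29.0% in the saddle of i-k K1 and i-i k1. Sense reads peaked at residues 171 to 180 of the protein in all 4 non-pigmented groups, at 241, 354, 78.0 and 192 CPM. Those of the hilum and of the i-i k1 saddle peaked there too. In the i-k K1 saddle residues 211 to 220 lay slightly above (1.89 against 1.80 CPM). In Clark, antisense reads of non-pigmented tissue peaked at residues 111 to 120, with 20.3 CPM in i-k K1 and 91.1 CPM in i-i k1. In Williams they peaked at residues 261 to 270 in both parts. The last peak is set by library: the antisense tag CAATCCCGGGAACATCCTTGA, which begins there, reached 150 to 446 CPM in the 4 Williams replicate 2 libraries and at most 3.35 CPM in any other.

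**Figure D2:**
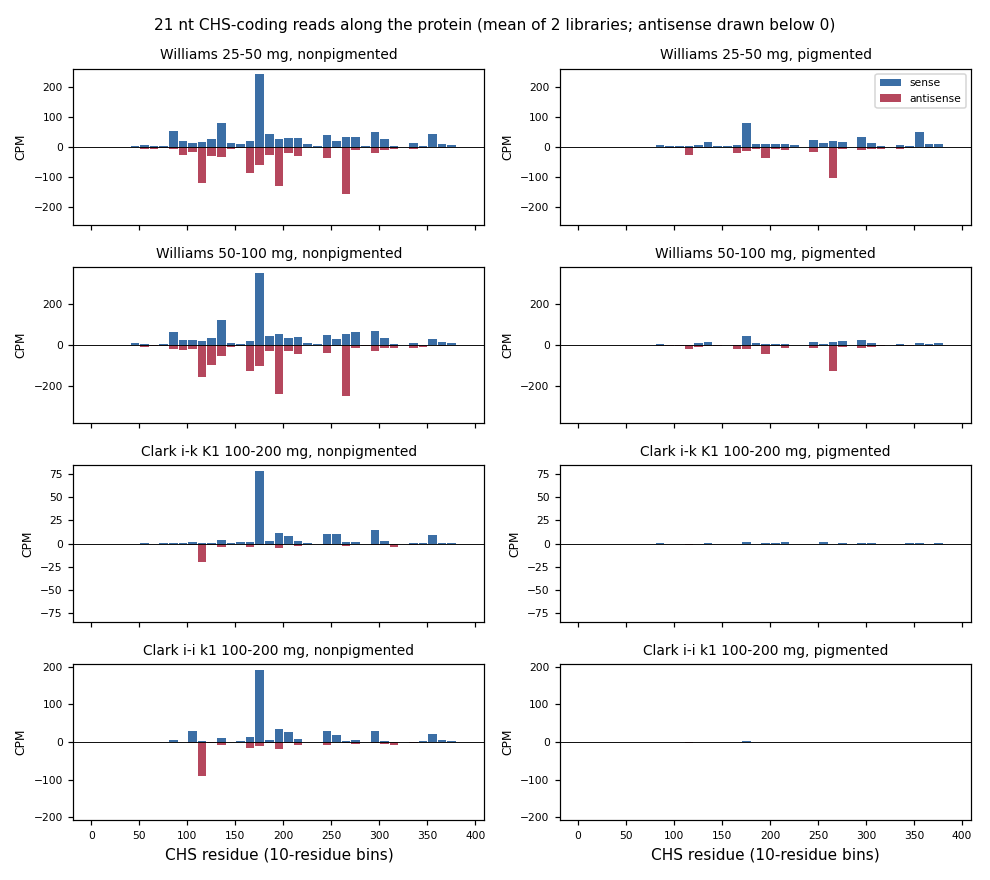
Reads of 21 nt along the CHS protein, in CPM per bin of 10 residues, as the mean of 2 libraries per group, with sense reads above 0 and antisense reads drawn below; each line and stage keeps its scale in both parts. Sense reads of non-pigmented tissue peak at residues 171 to 180 in each panel of the left column.

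Among listed families, miR393 rose and miR166 and miR164 fell in pigmented tissue, all in the paired fit. miR393, which targets auxin receptors of the TIR1 type, averaged 29.4 CPM in pigmented and 6.75 CPM in non-pigmented libraries (log2 fold change 2.02, SE 0.27, adjusted p = 7.4e-11), higher in 8 of 8 pairs. miR166, which targets class III HD-ZIP transcription factors, averaged 1554 and 3325 CPM (log2 fold change −1.15, SE 0.21, adjusted p = 3.1e-06), lower in 7 of 8 pairs. This family count leaves out the early-start miR166 tag described below, so it does not cover all miR166 reads. miR396, which targets growth-regulating factors, rose by 0.9985 (SE 0.23, adjusted p = 2.0e-04), higher in 7 of 8 pairs. miR164, known to target NAC transcription factors, changed by −1.52, miR168, the regulator of Argonaute1, by −0.78, and the legume family miR1511 by −0.60. Fragments of tRNA-His changed by −0.65.

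The paired limma fit over the mean of the 4 sets called 15 of 44 families, 4 higher and 11 lower. The unpaired limma voom fit called 0, with 4 at an unadjusted p under 0.05, and limma trend also called 0. With no scaling factor miR1511 and tRNA-His fragments stayed below 0, at −0.51 and −0.57, but lost the call. No named family changed direction under another scaling. Without the 4 Williams replicate 2 libraries, the unpaired fit called 4 families: miR393, miR1512, miR172 and miR1513.

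By list, the development families had 1 higher (miR396) and 4 lower (miR164, miR166, miR171 and miR172) of 12 in the paired fit, and the same counts adjusted over the list alone. miR172, which targets AP2-type factors, changed by −1.98 and miR171, which targets GRAS factors, by −1.44; both lay below 10 CPM. The 7 legume families had 1 higher (miR1512) and 3 lower (miR1511, miR1513 at −1.55 and miR3522 at −1.70), unchanged in number when adjusted over the list alone. The 10 phasiRNA triggers had miR393 higher and miR390, which starts the TAS3 pathway, lower at −1.63, again the same counts adjusted over the list alone. Of the 4 families that target silencing genes, miR162 (Dicer-like1) rose by 0.79 and miR168 fell by 0.78; adjusted over the list alone, 1 was higher and 2 were lower, the second being miR403 at −1.13.

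Of 5 nutrient and copper families, miR398 alone passed, at −1.54, and also when adjusted over the list alone. In Williams at 50 to 100 mg the paired fit called 0 of these, and miR395, miR398 and miR399 (−1.59, −1.99 and −1.99) passed when adjusted over the list alone. Of 5 tRNA fragments, tRNA-His passed, and 0 passed when adjusted over the list alone, by limma voom paired or unpaired and with 2 (tRNA-His and tRNA-Glu) at an unadjusted p under 0.05 in the paired fit. The pigment list had a single measured family, miR828, which targets MYB regulators of anthocyanin genes; its value was −1.03 (adjusted p = 0.183). By set it was −0.23 and 0.29 in Williams at 25 to 50 and 50 to 100 mg, −0.49 in Clark i-i k1 and −3.67 in Clark i-k K1, where it passed over its list alone but rested on 38 reads in a single non-pigmented library against 0 or 1 in the other 3. In the paired fit no list moved in a single direction by fry (adjusted p from 0.0935 to 0.497), while the mixed test passed for development (1.8e-04), phasiRNA triggers (4.5e-04) and legume families (5.3e-04). Unpaired, the mixed test passed for none of these (adjusted p = 0.829, 0.812 and 0.222). In the unpaired fit, miR393 and miR1512 alone passed when adjusted over their lists alone.

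**Figure D3:**
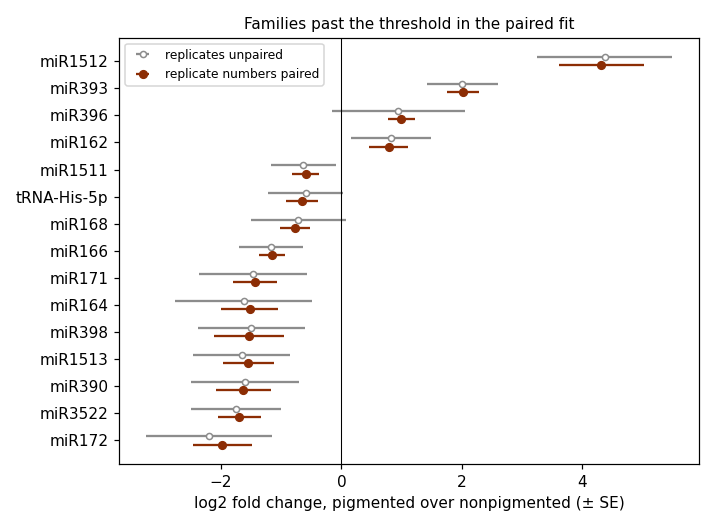
Log2 fold change, pigmented over non-pigmented and averaged over the 4 sets of line and stage, for the 15 families called in the paired fit, with SE as horizontal bars; open symbols are the unpaired fit. Of these, 4 lie above and 11 below 0; the value of miR1512 rests on groups with libraries at 0 reads.

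Of these families, miR393 and miR1512 were called in 3 of the 4 single lines and stages, all but Clark i-k K1. In Williams at 25 to 50 mg the paired fit called 6 families (unpaired 0, with 1 at an unadjusted p under 0.05; limma trend 0). Among these, miR393 changed by 2.29, miR396 by 1.56, and miR172 by −2.75, and tRNA-Asp fragments by −1.83. At 50 to 100 mg it called 11 families, 2 higher and 9 lower (unpaired 0, with 2 unadjusted; limma trend 0). There miR393 changed by 2.69, miR164 by −2.29, miR168 by −2.06, miR166 by −1.53, miR156, which targets SPL factors, by −1.49, miR319, which targets TCP factors, by −1.34 and miR1511 by −1.20. The calls of tRNA-Asp, miR156 and miR319 were limited to these single stages and absent from the mean over 4 sets. Clark i-i k1 gave 3 in the paired fit (unpaired 0, with 2 unadjusted; limma trend 0): miR393 at 1.95, miR166 at −2.02 and miR1512. Clark i-k K1 gave 0 in the paired and unpaired limma fits and in limma trend, with 7 and 0 at an unadjusted p under 0.05.

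miR1512, a legume family, was low but almost restricted to pigmented tissue. In Clark i-k K1 it had 6 reads in a single saddle library and 0 in the other 3 libraries. It had 53 to 289 reads per pigmented Williams library and 0 to 10 in the non-pigmented ones. In Clark i-i k1 it had 25 and 14 reads in the saddle and 0 in both libraries of the rest, which allows up to 0.0505 and 0.0697 CPM at a floor of 3 reads per library.

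Single CHS-coding tags are part of the reads summed above, so they give no separate support. In the paired fit of the mean over 4 sets, 321 of 30762 tags passed, 37 higher and 284 lower in pigmented tissue. Of the CHS-coding tags tested, 86 were lower and 0 higher, and 189 of the 284 were 21 nt long. The sense CHS tag TTGGCTGAGAACAACAAGGGT fell by 4.86 (SE 0.57, adjusted p = 0.0019), from 26.8 to 242 CPM per non-pigmented library to 0.0783 to 70.9 CPM per pigmented library. The antisense tag CAATCCCGGGAACATCCTTGA changed by −3.44, and its 4 pigmented Clark libraries had 0 reads. It was abundant only in the Williams replicate 2 libraries, so this mean rests largely on libraries where it was scarce. In Williams, antisense 21 nt reads of its bin, residues 261 to 270, fell less. They averaged 105 CPM in the hilum and 157 CPM in the rest at 25 to 50 mg, and 126 and 250 CPM at 50 to 100 mg. Outside CHS, the miR396 tag TTCCACAGCTTTCTTGAACTT rose by 1.16 and a miR166-related tag of 22 nt, TTCGGACCAGGCTTCATTCCCC, fell by 1.37.

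The unpaired limma voom fit called 0 tags in the mean over 4 sets, with 208 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0958; limma trend called 7. Without the 4 Williams replicate 2 libraries it called 80 tags, 48 of them CHS-coding and lower, and 78 were among the 321. In single sets the unpaired fit also called 0 tags, with 46, 206, 405 and 101 unadjusted in Williams at 25 to 50 mg, Williams at 50 to 100 mg, Clark i-k K1 and Clark i-i k1. The paired fit called 0, 17, 80 and 89, and limma trend 0, 0, 3 and 0. Without the base 4 variants described below, the paired counts of the last 3 were 28, 50 and 96. In Clark i-i k1, 58 of the 87 lower tags were CHS-coding. In Clark i-k K1, CAGAGTTCTACAGTCCGACGATC, part of the Illumina 5′ adapter, was among the lower tags at −3.20, with 465 and 1120 CPM in the rest of the seed coat.

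A miR166-related tag that starts upstream of the listed miR166, TCTCGGACCAGGCTTCATTCC, rose in the Clark saddle and in the mean over 4 sets, while the family fell in that mean. The family count leaves this tag out, as the tag does not begin with a listed sequence. The fall of the family therefore does not cover this form, and both forms together were not tested. For this tag the paired fit gave 2.30 over the mean of 4 sets (SE 0.25, adjusted p = 0.0013), 4.66 in Clark i-k K1 and 4.33 in Clark i-i k1, and the unpaired fit called it in none of these. Neither Williams stage called it: at 50 to 100 mg it had 413 CPM in the hilum and 948 CPM in the rest in replicate 1 and 130 and 102 CPM in replicate 2, and at 25 to 50 mg 1691 and 824, and 50.7 and 43.3 CPM. Its ratio to the listed tag TCGGACCAGGCTTCATTCCCC, chosen for study after these values were seen, was 0.990 to 1.497 in the Clark saddle and 0.0085 to 0.0602 in the rest. In Williams the ratio was 0.0457 to 0.600 in the hilum and 0.0203 to 0.311 in the rest. The log2 ratio was higher in pigmented tissue in 8 of 8 pairs, by 3.50 on average (two-sided exact permutation p = 0.0108).

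**Figure D4:**
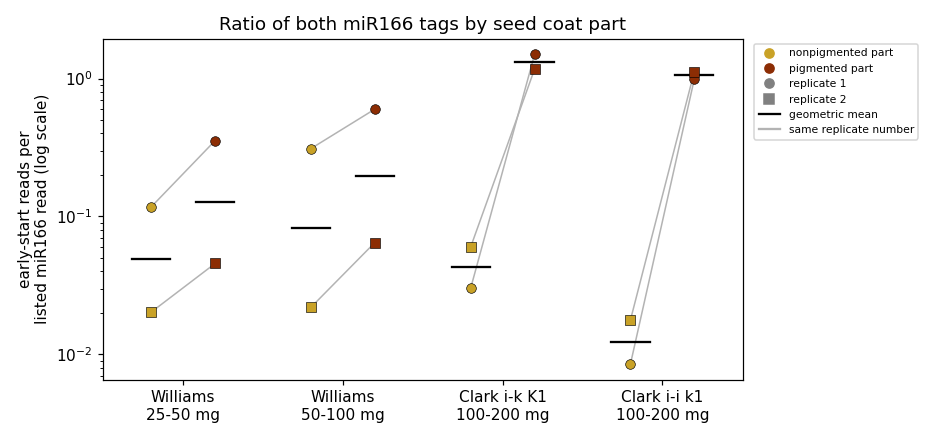
Reads of the early-start miR166 tag per read of the listed miR166 tag in each library, on a log axis; symbols give the replicate, grey lines join libraries of the same number and black bars are geometric means. The ratio rises from non-pigmented to pigmented tissue in 8 of 8 pairs, by a mean log2 difference of 5.69 in Clark and 1.32 in Williams.

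The isolines carry different alleles at both K1 and I, so their comparison does not separate the loci. CHS-coding RNA was 1092 ± 114 CPM in non-pigmented i-i k1 and 352 ± 213 CPM in i-k K1 tissue, and 36.9 ± 1.73 and 37.2 ± 12.4 CPM in the saddle (SD, n = 2 each). In non-pigmented tissue both i-i k1 libraries (1011 and 1172 CPM) lay above both i-k K1 libraries (503 and 201 CPM), but limma called neither part (1.51, SE 1.42, adjusted p = 0.981; saddle −0.30, SE 1.65, adjusted p = 0.966). A permutation over all 8 Clark libraries did not pass either (log2 difference 0.90, two-sided exact p = 0.571; the smallest possible is 0.0286); it mixed both parts, so its spread includes the difference between parts. None of 44 miRNA and tRNA families passed between isolines in either part by limma voom, by the paired fit or by limma trend, and 0 had an unadjusted p under 0.05. These fits pool the spread of all 16 libraries, including the Williams replicates that agreed poorly. No isoline fit without those was run, so differences between isolines could be missed. Argonaute5 of other plants is known to prefer small RNAs that start with C. The share of 21 nt reads that start with C was 16.9% ± 2.45 in i-i k1 and 19.4% ± 1.91 in i-k K1 (SD, n = 4; exact permutation p = 0.171, adjusted p = 0.294 over 12 shares). No other first base of 21, 22 or 24 nt reads passed, with a smallest adjusted p of 0.171. The smallest possible p, 0.0286, passes over 12 shares only if many of them reach it, so the test could hardly pass. Reads of 22 nt that start with C reached it (19.8% in i-i k1, 22.5% in i-k K1), as did 21 nt reads that start with T (23.1% and 25.8%). Reads of 24 nt that start with C did not (23.6% and 26.1%, exact permutation p = 0.143).

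Between isolines, limma called 1530 tags in non-pigmented tissue, 6 higher and 1524 lower in i-i k1, and 1760 in the saddle, 1 higher and 1759 lower. The paired fit called 30 higher and 1663 lower, and 38 higher and 1861 lower. Of the 1806 tags lower in either part, 77.4% differed at base 4 alone from a tag at least 10 times as abundant in the i-k K1 libraries. In those libraries 12.4% of reads had base 4 uncalled. The tags with the largest decreases at 50 CPM or more, such as AATGGACGGAAGGGCACC (−12.85 and −12.81) and AATAGACGGAAGGGCACC (−11.44 and −10.27), were of this kind. Without such tags 0 passed in either part by limma, unpaired, and 171 and 317 in the paired fit. All i-k K1 libraries came from a single library set, so line and set cannot be told apart; without i-i k1 replicate 1 of the same part the calls were 0 and 0, and without replicate 2 they were 221 and 615.

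**Figure D5:**
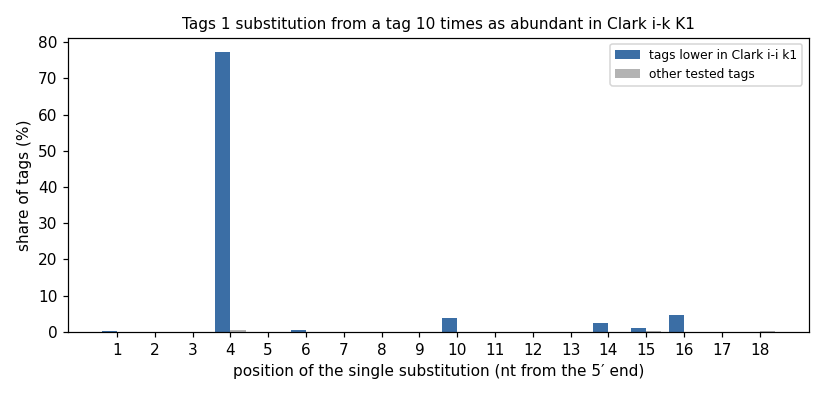
Share of tags, in percent, that lie 1 substitution from a tag at least 10 times as abundant in the Clark i-k K1 libraries, by position of the substitution from the 5′ end, for the 1806 tags lower in i-i k1 and for other tested tags. Base 4 holds 77.4% of the lower tags and 0.522% of the others, and the highest other position, base 16, holds 4.71%.

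The difference between parts was also compared between the isolines. No tag differed in its part effect (limma voom 0, with 19 at an unadjusted p under 0.05; paired fit 0, with 3080 at an unadjusted p under 0.05 and a smallest adjusted p of 0.405; limma trend 0). For CHS-coding RNA the part effect was 1.84 log2 units more negative in i-i k1, which did not pass in the paired fit (−1.84, SE 0.69, adjusted p = 0.231).

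Between stages of Williams, CHS-coding RNA had the levels given above, and neither part differed by limma (adjusted p = 0.987 in the rest of the seed coat and 0.807 in the hilum). No tag passed between 50 to 100 mg and 25 to 50 mg seeds. The limma voom fit called 0 in each part, with 717 at an unadjusted p under 0.05 in the rest of the seed coat and 496 in the hilum, and the paired fit and limma trend called 0. Williams replicates correlated at only 0.322 to 0.4998, and no fit held a term for their library sets. These results therefore do not show that the stages are alike.

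The shares of small RNA by length did not differ detectably between the parts. Reads of 21 nt, the usual size of miRNAs and of siRNAs that act on messenger RNA, made 12.6% ± 1.65 of pigmented and 12.9% ± 1.76 of non-pigmented libraries (SD, n = 8). Reads of 24 nt, typical of siRNAs that guide DNA methylation, made 10.97% ± 5.43 and 12.1% ± 7.24. None of the 5 lengths from 20 to 24 nt differed by exact permutation (adjusted p = 0.654 for each), and pairing left the adjusted p between 0.410 and 0.555.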

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

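The tests of the isoline tags, of CHS-coding RNA and of the miR166 tags reported here were chosen only after the results were seen.

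The part difference of CHS-coding RNA passed a limma F test over the 4 sets of line and stage (paired fit, adjusted p = 7.5e-05). The values were −1.55 and −2.99 in Williams at 25 to 50 and 50 to 100 mg. They were −3.23 in Clark i-k K1 and −5.07 in Clark i-i k1. CHS-coding RNA was added to the family table for this test, which changed fold changes slightly from those of the table without it. miR168 also passed, at −0.23, −2.09, 0.35 and −1.16 in the same order (adjusted p = 0.0459), as did 5′ fragments of tRNA-Asp, at −1.79, 0.88, 0.21 and −0.12 (adjusted p = 0.0459). The F tests rest on a spread shared over all sets and borrowed in part from the other families. CHS pairs were close in Williams at 25 to 50 mg (−1.48 and −1.49) and Clark i-i k1 (−4.73 and −5.04). They lay apart in Clark i-k K1 (−4.14 and −2.13) and in Williams at 50 to 100 mg. Whether the sets differ beyond the spread of CHS pairs was not tested. Reads with an uncalled base, left out of every tag, made 12.7% of the i-k K1 libraries.

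The lower CHS-coding RNA of pigmented parts held for antisense reads of 21 nt, at −3.78 (exact permutation p = 0.0062), lower in 8 of 8 pairs, which breakdown of CHS messenger RNA would not give. Relative to reads of miRNA families it was −2.75 (p = 0.0015, the smallest these permutations can give), again in 8 of 8 pairs, so scaling does not account for it. After reads that match the reversed protein were subtracted it was −3.36 (exact permutation p = 0.0031). This step took a larger share from the pigmented library in 8 of 8 pairs. It could therefore only enlarge the difference and is no test of chance matches. Such matches made 3.89 to 17.7 CPM per library, against 201 to 5892 CPM of CHS-coding reads in non-pigmented tissue. A stricter limit first set, under 1% of such reads in each non-pigmented library at 21 nt, was exceeded in Clark i-k K1 replicate 2 with 5.68%. A candidate explanation is that siRNAs from CHS genes are less abundant where pigment forms. This is a hypothesis found and tested on the same data, and which CHS copies the reads come from stays open.

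The tags lower in i-i k1 fit miscalled bases in the i-k K1 libraries: 77.4% of them have a far more abundant partner that differs at base 4, against 4.71% at the highest other position. The other 409 tags have no such partner, but 230 of them (56.2%) have an abundant partner at another of the first 18 bases, against 0.913% of other tested tags, so miscalls elsewhere could account for many; for the rest, set and isoline cannot be told apart. Without base 4 variants 0 tags passed, which had first been taken as the sign of no other difference. The fold changes of the 409 stayed, with a median of −5.47 before and −5.48 after, while the smallest adjusted p rose to 0.0506 and 0.0915, and why they lost the call was not tested.

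The part difference of the miR166 tag ratio was larger in Clark (5.69 ± 1.07) than in Williams (1.32 ± 0.31) by 4.37 log2 units (SD, n = 4 pairs each; exact permutation p = 0.0286, the smallest possible). A ratio within a library is free of scaling, and it was 3.50 higher in pigmented parts on average. The mean over each of the 4 sets was positive, from 1.36 to 4.95, but this follows from the 8 positive pairs and is no separate test of the set. A candidate explanation is a change in where the miR166 precursor is processed, or in which of its loci is active; the table of symbols holds 20 MIR166 loci, and these were not tested. Clark and Williams also differ in tissue and seed weight, so the difference between them cannot be assigned to the line.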

How the results depend on the processing

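Tests added only after the results were seen were limma trend, the removal of base 4 variants, the removal of whole library sets, rescaled paired values of single families and the CHS ratios. Of 298 alternative values for 21 results, 261 were classed as unchanged. Most of these results are counts of tags or families called. A count was classed as unchanged when it was equal to the main count or within 1.5 times of it. The main count was 0 in every comparison except the tags between isolines. A count that stayed at 0 says little about stability. Only results with a direction could reverse, and none did. The CHS difference between parts passed under each alternative run, the isoline difference in CHS under none, and length shares and first bases stayed unpassed. For first bases this says nothing about stability, since that test could hardly pass under any setting, for the reason given in the Results. Exchanging isolines within replicate number leaves too few arrangements to pass. Without Williams replicate 2 the CHS difference was −3.41 (exact permutation p = 0.0139), and without Clark i-k K1 it was −3.14 (p = 0.0185). Paired values of 70 single family fold changes under other scalings kept direction and call in 68.

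With each replicate pair as a block, tags past the threshold moved from 0 to 17 in Williams at 50 to 100 mg, 80 in Clark i-k K1, 89 in Clark i-i k1 and 321 in the mean over 4 sets, and families from 0 to 6 and 11 in the Williams stages, 3 in Clark i-i k1 and 15 in the mean over 4 sets. Of the other total counts of tags or families, the block moved none by over 1.5 times. Within the isoline totals it moved tags higher in i-i k1 from 6 to 30 and from 1 to 38, and it brought CHS-coding RNA past the limma threshold in the 4 single sets and some lists past the mixed fry test. With the block and without base 4 variants, tags were 28, 50, 96 and 328, and 171 and 317 between isolines in the non-pigmented part and the saddle. Without base 4 variants alone the isoline counts were 0 and 0. For the mean over 4 sets, leaving out Williams replicate 2 gave 80 tags and 4 families, or 67 and 15 with the block, and leaving out Clark i-k K1 gave 373 and 16 with the block. Limma trend gave 3 tags in Clark i-k K1 and 7 in the mean over 4 sets. At 1 CPM the counts were 4 in the mean over 4 sets, and 7821 and 8805 between isolines; 20 to 24 nt tags gave 765 and 930, as fewer were tested. Families at 1 read or more gave 1 in the mean over 4 sets. With 1 library left out in turn, isoline counts ran from 0 to 1540 and from 0 to 1500, and families in the mean over 4 sets from 0 to 2 (1 without Williams 25 to 50 mg non-pigmented replicate 2 or 50 to 100 mg hilum replicate 1, and 2 without hilum replicate 2). A lone library was then assumed to vary like the other groups. The cause was not tested except where stated.

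The scaling moved the median tag by over 0.1 with no factor in Clark i-i k1 parts (0.18), between isolines (0.25 and 0.33) and between stages (−0.38 and −0.43), and with median-of-ratios factors between isolines in the saddle (−0.19) and in the difference of part effects (−0.11). The DESeq2 test, matches to CHS7 or CHS8 alone, matches with a mismatch and all counts per gene were not run.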

Other observations

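The split counts were planned beforehand, and the leave-outs of whole library sets were chosen only after the results were seen.

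Beyond CHS, 198 of the 284 tags lower in pigmented parts did not match the CHS protein. These 198 had a median log2 fold change of −1.99, and 113 of them were 21 nt long. The 86 CHS-coding tags had a median of −3.40 and ranged from −5.56 to −1.56. The 37 higher tags had a median of 1.85, and 14 of them were 21 nt long. In the saddle, the paired fit of the isolines found AAGTCCTCGTGTTGCACCTCT (2.38) and GAAGTCCTCGTGTTGCACCTCT (2.74) higher in i-i k1, with adjusted p of 0.0428 and 0.0144, and 0.0934 and 0.0795 unpaired.

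In the paired fit, 1 of 100 splits that part all 8 pairs, the real split itself, called as many tags as the 321 found, and the highest other split called 120. For families it was 1 of 100 as well, with 15 called and 9 in the highest other split. Other splits with any call numbered 9 for tags and 7 for families. With 100 of 128 possible splits drawn, both counts lay above the others drawn. This does not show which tags or families differ. In the unpaired fit the real split called 0 tags and 0 families, so all 100 of 100 drawn splits called as many in either table; a count of 0 fixes that outcome, which therefore says nothing about chance. Of these, 13 splits called more tags, up to 19298, and 27 called more families, up to 25. Those many calls point to a structure of the samples, since the drawn splits that part all pairs as the real split does called 0. With the Williams replicate 2 libraries left out, the unpaired fit called 80 tags and 4 families.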
